A study of Mus musculus with 4 samples.

How the data were processed

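RNA abundance was measured in C2C12 cells, an established mouse myoblast line, on 4 arrays of spotted cDNA clones. Per the labels' protocols, proliferating cells received either an siRNA that targets HuR or a control siRNA, RNA was extracted with phenol and chloroform, and it was reverse transcribed with a 33P-labelled nucleotide. Each array thus carries 1 radioactive signal per spot and no second channel. Groups and replicate numbers came from the sample titles, which name 2 arrays per siRNA. The labels do not say whether the 2 arrays of a group came from separate cultures, so every p-value measures the spread between these arrays, which may be technical. Column names of the deposited table were matched to the sample titles by siRNA and number, although the table itself is named after siRNA against NPM.

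The authors deposited z-scores, a score with no unit of its own, and not spot intensities. This was read from the values: each array has 16896 spots in 2 sections of 8448, the grid numbering restarts at the second section, and within each section of each array the mean is 0 and the SD is 1. Values have 2 decimals. Scanner, background correction, log base and the z-transformation are not given in the sources used here, so 1 z unit is 1 SD of the values in an array section, and no fold change can be computed. The second deposited table held the same scores, equal in all 67584 cells compared. Between 104 and 131 spots per section and array shared 1 most frequent value. By comparison, the 10 nearest values were each held by a median of 4 to 5.5 spots in the second section and 40.5 to 47 in the first, and 471 spots had the most frequent value on at least 1 array. These spots were kept, and leaving them out was tried.

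Of the spots, 16838 carried a clone with an accession, 52 were described as empty and 6 had no accession. Clones were named through the gene IDs, RefSeq accessions or symbols in the deposited table, updated with the RefSeq gene table of the GRCm38.p6 assembly, which served for names only. A current symbol was found for 9497 clone spots (56.4%), and 147 clone spots whose identifiers disagreed were left unnamed. No coordinates are given, because the deposited table names no genome build. Spots of 1 clone were averaged, and of several clones of a gene the one with the highest mean over all 4 arrays was used. This left 14062 features, of which 6726 had a gene symbol and 7336 were unnamed clones.

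The design fixed before the data were examined foresaw quantile-normalised log2 signals. Because the deposited values were already z-scores, they were used as deposited, with no further normalization. Quantile normalization within each section was added as an alternative, and it changes the count of calls from 0 to 1. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no block), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. A comparison of 2 against 2 arrays cannot reach an exact permutation p below 0.333, and limma's test instead borrows the spread of all features. Gene lists with at least 5 measured members were tested with camera (preset correlation of 0.01 between genes). Camera with an estimated correlation and fry were run beside it.

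Genes were named by a rule. Elavl1, Npm1 and Khsrp were always named. For each direction 10 genes followed: the genes past the threshold by size and, where fewer passed, the genes of smallest unadjusted p in the upper 50% of mean level whose 2 HuR siRNA arrays lay on the same side of both control arrays. Of a list past the set test 4 members were to be named, and of other lists the members past the threshold, which were none. The 2 members of smallest unadjusted p of each list were added after their values were seen. Some genes picked this way are not reported here, which leaves 9 genes per direction, and they stayed in all counts and list tests.

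The steps were tested on simulated data with the measured means and fitted spread of the 14062 features, 200 of them changed in each of 10 draws. At an adjusted p under 0.05, 0.2% of changes of 0.25 z units were recovered, 41.6% of changes of 0.5, 86% of changes of 1 and 98.2% of changes of 2, with 53 false calls over the 10 draws. A shift of 0.05 z units in the 38 measured genes of the nucleolar list was called in 8 of 10 draws, and other lists were called 2 times over these draws. Features were drawn independently of each other, without the source plate or replicate structure of the arrays, so these rates may be too favourable. Each draw also mixed all of these sizes, and the large changes ease the adjusted threshold for the small ones. The rates therefore do not hold where only a few features change. In the measured data Hmgn2, with a difference of -0.535 (SE 0.039), had a limma adjusted p of 0.481. The number of arrays limits the precision: the median SE of a difference was 0.052 z units and the median half-width of its 95% interval was 0.14.

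Alternatives covered the normalization, filters on dim features, the handling of several clones, a replicate block, an intensity trend and leaving out each array. Removal of the medians of print grids or of the 96-well source plates named in the deposited table was added after the data were seen.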

Results

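The series compared mouse C2C12 myoblasts, a line of muscle precursor cells, after transfection with siRNA against HuR or with a control siRNA. HuR, encoded by Elavl1, is an RNA-binding protein that binds AU-rich elements of mRNAs. The title names 2 further genes, nucleophosmin (Npm1) and the RNA-binding protein KSRP (Khsrp), and the comparison addresses which transcripts differ when HuR is targeted. There were 2 arrays per group with 16896 spots each, and values are z-scores, so that a difference of 1 unit equals 1 SD of the values in an array section.

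Elavl1 (gene ID 15568), the targeted gene, did not differ detectably between the groups. Its brighter clone had a mean z-score of -0.205 ± 0.007 (SD, n = 2) on the arrays labelled HuR siRNA and -0.16 ± 0.057 (SD, n = 2) on the control arrays. The difference was -0.045 (SE 0.047, 95% interval -0.172 to 0.082, limma adjusted p = 0.991). A second Elavl1 clone, listed under an older symbol, differed by 0.03 (SE 0.058) in the other direction. The arrays therefore give no measured reduction of the target mRNA. Whether these clones could show one was not tested, and the second clone (means of -0.45 and -0.48) lay below its section's median of -0.16. The deposited table is named after siRNA against NPM, an abbreviation of nucleophosmin, while the sample labels and its columns name HuR. An siRNA against nucleophosmin would be meant to lower Npm1, but both Npm1 clones lay higher on the arrays labelled HuR siRNA (0.33 and 0.205). That direction goes against the reading as siRNA against NPM, although neither clone passed the threshold. With no reduction of Elavl1 either, the values do not settle which siRNA was used. Groups are called here by their labels, so every difference, that of Npm1 included, carries this doubt.

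Npm1 (gene ID 18148), which encodes a nucleolar chaperone of ribosome assembly, lay higher on both arrays labelled HuR siRNA than on both control arrays, on each of its 2 clones. The brighter clone had z-scores of 0.315 ± 0.12 and -0.015 ± 0.078 (SD, n = 2 each), a difference of 0.33 (SE 0.079, 95% interval 0.117 to 0.543). The other clone differed by 0.205 (SE 0.057). Neither passed the threshold over all features (limma adjusted p = 0.991 for the brighter clone). Khsrp (gene ID 16549) was at 0.66 ± 0.028 and 0.675 ± 0.064 (SD, n = 2 each), a difference of -0.015 (SE 0.051) whose sign depended on the array left out and on the removal of grid medians.

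Across the 14062 features, 0 passed limma's test at an adjusted p under 0.05, and 528 (3.75%) had an unadjusted p under 0.05 where 703 are expected by chance. With the replicate number as a block 0 features passed and 858 had an unadjusted p under 0.05, so the side of the chance count depends on the block. Of the 528, 199 were higher and 329 lower on the arrays labelled HuR siRNA. The lower ones were unevenly spread over the source plates, with 26 on plate 57 and 13 on plate 70. The smallest adjusted p was 0.2042, shared by 2 unnamed clones whose control values were all the most frequent value of the section. With quantile normalization of the z-scores within each section, 1 of these clones passed. The quantile normalization foreseen before the data were examined was one of signals and could not be run. Without spots at the most frequent value the smallest adjusted p was 0.911. The arrays were parted by group without overlap at 1907 features that were higher and 1920 that were lower, together 27.2%. Chance gives 33.3% for values without ties. Equal values were not counted as parted and the scores have 2 decimals, so the share by chance is lower here and the gap decides nothing. Arrays of the same siRNA were no more alike than arrays of different siRNAs. Pearson's r across spots, which are not independent replicates, was 0.9829 and 0.9819 within groups and 0.9799 to 0.9843 between them.

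The named genes that lay higher with HuR siRNA were those of smallest unadjusted p. Ost4, a subunit of the oligosaccharyltransferase, differed by 0.275 (SE 0.042), Mgat2, an enzyme of N-glycan processing, by 0.31 (SE 0.05), and Spcs1, a subunit of the signal peptidase, by 0.16 (SE 0.039). Acta2, an actin of smooth muscle that myoblasts also express, differed by 0.44 (SE 0.092) and the actin-binding protein Lasp1 by 0.18 (SE 0.041). The ubiquitin ligase Ube3a (0.28, SE 0.052), the mitochondrial import receptor Tomm20 (0.2, SE 0.041), the annexin Anxa3 (0.39, SE 0.079) and Npm1 were the others. All 9 had an adjusted p of 0.991 and did not pass the threshold.

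Among the genes that lay lower, Hmgn2, which encodes a nucleosome-binding protein, had the smallest adjusted p of any named gene (0.481). Its only clone was at -0.14 ± 0.014 with HuR siRNA and 0.395 ± 0.007 with control siRNA (SD, n = 2 each), a difference of -0.535 (SE 0.039, 95% interval -0.64 to -0.43). The exchange factor Cyth2 (-0.415, SE 0.07), the kinase Map3k7 (-0.35, SE 0.064), the phosphatase Ptpn21 (-0.3, SE 0.045), the ubiquitin ligase Ltn1 (-0.295, SE 0.053) and the RNA-binding protein Rbm12 (-0.355, SE 0.066) followed. The clones of these 5 genes came from the same 96-well source plate, on which 26 of 85 features were lower at an unadjusted p under 0.05. The centrosomal gene Nin differed by -0.4 (SE 0.076), the nuclear export receptor Xpo4 by -0.62 (SE 0.121) and Atp5j2, a subunit of ATP synthase, by -0.21 (SE 0.042). Apart from Hmgn2 all had an adjusted p of 0.991.

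**Figure D1:**
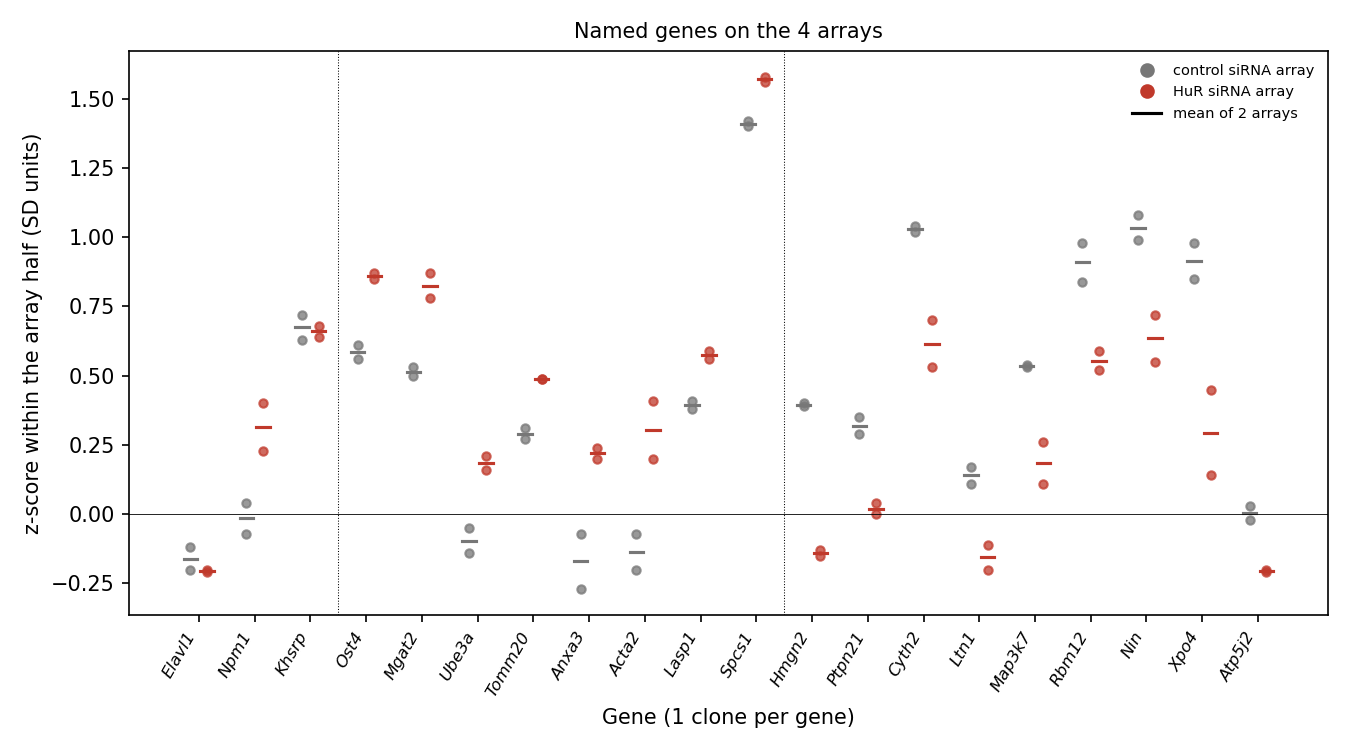
Z-scores of the named genes on the 4 arrays, with points for single arrays, bars for the mean of 2 arrays, grey for control siRNA and red for HuR siRNA. From left to right, divided by dotted lines, stand the 3 genes always named, the genes that lay higher and the genes that lay lower, and 0 of them passed the threshold.

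Most other clones of these genes differed by less than the named clone or in the other direction. The genes were named for a small p on their brightest clone, so smaller differences on other clones follow in part from that choice. The other clones of Mgat2, Ost4, Lasp1 and Rbm12 differed by 0, 0.05, 0.03 and 0.01, and those of Xpo4 by -0.06 and -0.03. The other clones of Ptpn21 differed by -0.04 and 0.02, and those of Tomm20 by 0.085 and -0.02. The other clones of Ube3a were at -0.105 and -0.02 and those of Nin at 0.35 and 0.05. Npm1 and Ost4 were the named genes with more than 1 clone whose clones all parted the arrays in the direction of the named clone, by 0.05 on the other clone of Ost4.

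Of the 27 gene lists fixed before the data were examined, 26 had enough measured members, and 0 passed camera at an adjusted p under 0.05. The lowest adjusted p was 0.249 with the preset correlation and 0.753 with an estimated correlation, and fry for a shift in 1 direction gave no list either (lowest adjusted p = 0.0781). At an unadjusted camera p under 0.05 stood 3 lists. Over all genes tested, 0 members of any list passed, and adjusted over the list alone 1 member passed, Hmgn2 among the histone and chromatin genes (adjusted p = 0.00318). In the groups described next, the examples are the members of smallest unadjusted p, chosen after their values were seen, and no example passed the threshold over all genes.

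Of the mRNAs described as HuR ligands, 35 of 50 were measured, 18 higher and 15 lower, with a mean difference of 0.004 (camera adjusted p = 0.898). The transcription factor gene Jun differed by -0.285 (SE 0.051) and Npm1 by 0.33. Fry's test for change in either direction, which does not compare a list with other genes, gave an adjusted p of 0.00544 for this list and 0.00855 for the histone and chromatin list. Each call was lost without 1 gene: Hmgn2 gave 84.3% of the summed squared t of the histone and chromatin list, whose adjusted p without it was 0.875, and Jun gave 30.7% for the HuR ligands, with 0.219 without it. Leaving out the strongest member weakens any list, so this alone decides little. The adjusted p was 0.122 and 0.136 once source plate medians were removed, and 0.287, 0.523 and 0.207 for the HuR ligands without HuR siRNA replicate 1, control siRNA replicate 1 and control siRNA replicate 2. For the histone and chromatin list it was 0.209, 0.379 and 0.207 without the same arrays. It was also 0.054 for the HuR ligands without the lower 50% of features by mean level and 0.0719 for the histone and chromatin list with the replicate block. The histone and chromatin genes had 15 of 31 members higher and 14 lower (camera adjusted p = 0.822).

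Genes of AU-rich element binding and mRNA decay were evenly spread, with 19 of 35 higher and 16 lower. Pan2, a deadenylase subunit, differed by -0.61 (SE 0.145) at a low level (mean z -2.56) and the deadenylase Parn by 0.085 (SE 0.056). Of the partners of HuR and nuclear export factors, 10 of 14 were higher and 3 lower. The export receptor Xpo1 differed by 0.105 (SE 0.046), with 1 of its values with HuR siRNA at the most frequent value of the section. Of the spliceosome and hnRNP genes, 26 of 57 were higher and 28 lower, with the splicing factor Sf3a3 at -0.16 (SE 0.049) and a low level (mean z -1.245). The camera adjusted p was 0.805, 0.475 and 0.622 for these lists.

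Of the myogenic regulators and muscle structure genes only 10 of 55 were measured, 8 higher and 2 lower, with a mean of 0.071 (camera adjusted p = 0.349). Acta2 differed by 0.44 and the fast myosin light chain gene Mylpf by 0.125 (SE 0.061). The actin cytoskeleton and adhesion list had 26 of 42 members higher and 14 lower (adjusted p = 0.575), with cofilin (Cfl1) at 0.155 (SE 0.047). Extracellular matrix and fibroblast markers were split 18 to 14 among 32 (adjusted p = 0.569). The collagen gene Col5a1 and the protease inhibitor gene Timp3 each differed by 0.215 (SE 0.044 and 0.072), and Col5a1 was at -0.018 when its clones were averaged.

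In the machinery of growth, 23 of 38 nucleolar and ribosome biogenesis genes were higher and 12 lower (adjusted p = 0.349), with Npm1 at 0.33 and Surf6, at a low level (mean z -1.615), at 0.35 (SE 0.067). Cytosolic ribosomal protein genes had 45 of 71 members higher and 26 lower and a mean of 0.02 (adjusted p = 0.349). Without HuR siRNA replicate 1 that mean was 0.051 and passed camera with the preset correlation (adjusted p = 0.00209) but not with an estimated one (adjusted p = 0.923 with an estimated correlation), and without HuR siRNA replicate 2 it was -0.011. Translation factors stood at 20 higher and 16 lower of 38 (adjusted p = 0.575), with Eif1ax at 0.14 (SE 0.043). The G1/S and DNA replication list had 25 of 39 higher and 12 lower (adjusted p = 0.356), with the ribonucleotide reductase genes Rrm2 and Rrm1 at 0.135 (SE 0.051) and 0.15 (SE 0.061). The G2/M and mitosis list had 21 of 43 higher and 22 lower (adjusted p = 0.822). Its kinase gene Ttk differed by 0.52 (SE 0.087), but its level was low (mean z -1.765) and both of its values with HuR siRNA were the most frequent value of the section.

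In energy metabolism, oxidative phosphorylation genes had 19 of 54 members higher and 35 lower, with a mean of -0.02 (adjusted p = 0.356). Without the lower 50% of features by mean level the mean was -0.037 and passed camera with the preset correlation (adjusted p = 0.0305) but not with an estimated one (adjusted p = 0.726 with an estimated correlation). Atp5j2 differed by -0.21 and Ndufc1, a subunit of complex I, by 0.265 (SE 0.044). Mitochondrial ribosome genes were 27 higher and 20 lower of 48 (adjusted p = 0.569), glycolysis genes 10 and 8 of 18 (adjusted p = 0.855), and cholesterol synthesis genes 9 and 2 of 11 (adjusted p = 0.569). Hexokinase 1 (Hk1) differed by -0.145 (SE 0.056).

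Stress and turnover lists did not pass either. Protein folding and heat shock genes were 15 higher and 10 lower of 28 (adjusted p = 0.569), with the co-chaperone gene Dnajb4 at -0.31 (SE 0.085) and Bag1 at 0.15 (SE 0.045). Endoplasmic reticulum stress genes were 10 higher and 11 lower of 22 (adjusted p = 0.575), with the phosphatase subunit gene Ppp1r15a at 0.16 (SE 0.039) and the isomerase gene Pdia6 at 0.155 (SE 0.046). Proteasome genes were 13 and 19 of 36 (adjusted p = 0.998), and p53 targets and apoptosis genes 9 and 10 of 20 (adjusted p = 0.663). Interferon and double-stranded RNA response genes were 6 and 5 of 12 (adjusted p = 0.924), with B2m at 0.14 (SE 0.046) and Ifitm3 at -0.14 (SE 0.062). Immediate early genes were 10 and 4 of 14 (adjusted p = 0.569).

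Markers of other cell types gave few measured genes. All 5 measured blood, macrophage and endothelial markers were lower, with a mean of -0.108 (adjusted p = 0.249), and the endothelial cadherin gene Cdh5 was at -0.285 (SE 0.131) and a low level (mean z -1.292). Neural and glial markers were 4 higher and 1 lower of 6 (adjusted p = 0.521), with nestin (Nes), which myoblasts also express, at 0.225 (SE 0.088). Adipocyte markers were 3 and 3 of 6 (adjusted p = 0.924). The osteoblast and chondrocyte list had 4 measured members, too few for the test, of which 3 were lower. Median, mean and test differed in sign for the mRNA decay, glycolysis, G2/M, p53, proteasome and endoplasmic reticulum stress lists.

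**Figure D2:**
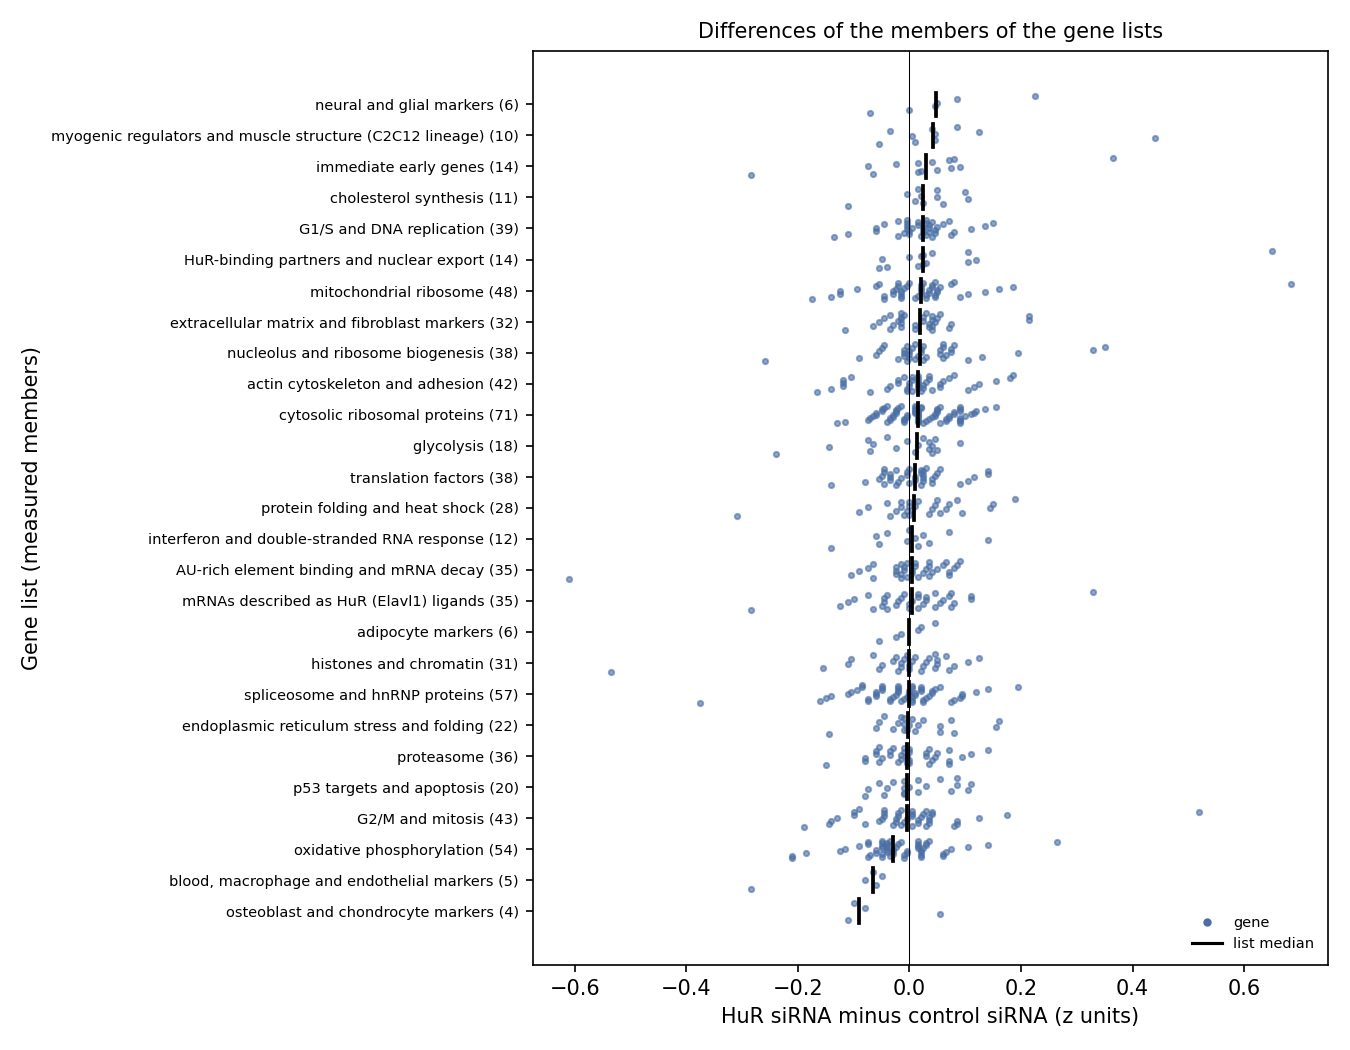
Differences between HuR siRNA and control siRNA in z units for the measured members of the 27 gene lists, with points for genes, bars for list medians and the number of measured members in brackets. Medians lay between -0.09 and 0.048, and 0 of the 26 lists tested passed camera.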

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

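A signal appeared in spots outside the comparison. Of the 52 spots described as empty, 19 had a z-score above 0 on all 4 arrays, with means of 0.51 to 2.14, and 33 were below 0 on all 4. The 19 lay in grids 266 to 311, which held 28 of the empty spots. Their mean difference between HuR siRNA and control siRNA was 0.013 (SD 0.059 over spots). The look at these spots by grid was chosen after their values were seen. The 2 Npm1 clones lay within the same range of grids, in grids 302 and 304 of the second section. No explanation was tested, nor was what this means for the Npm1 values.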

How the results depend on the processing

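The removal of grid medians, of source plate medians and of spots at the most frequent value, were chosen as alternatives after seeing the data, as was quantile normalization, which had been foreseen as the main setting. Background correction and the z-score alternative were not run, since the values were z-scores already, and the second deposited table held equal values. The count of features past the threshold was 0 under all alternatives except quantile normalization (1 unnamed clone that was lower and at the most frequent value on both control arrays, adjusted p = 0.0238, with a range of the smallest limma adjusted p of 0.0238 to 0.911 over the alternatives). The cause was not tested. Features at an unadjusted p under 0.05 numbered 413 to 679 elsewhere, 278 without the lower 50% by mean level, where fewer features were tested, and 858 with the replicate block, above the 703 expected by chance. With the replicate block, 0 features and 0 lists passed. The deviations of same-numbered arrays correlated at 0.1. The labels do not say what a number marks, and 2 pairs are too few to show whether the numbers pair the arrays.

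Elavl1 ranged from -0.11 to -0.005 over the alternatives (adjusted p 0.705 to 0.998) and Npm1 from 0.245 to 0.415 (adjusted p 0.585 to 0.998). Leaving out each array assumes that the lone array of a group varies like the other group. Between 0 and 1 lists passed camera when an array was left out, the 1 being cytosolic ribosomal proteins without HuR siRNA replicate 1 (mean 0.051, adjusted p = 0.00209, range over the alternatives 0.00209 to 0.898, and adjusted p = 0.923 with an estimated correlation). Without the lower 50% by mean level 1 list passed, oxidative phosphorylation (mean -0.037, adjusted p = 0.0305, range 0.0305 to 0.782, and adjusted p = 0.726 with an estimated correlation). The cause was not tested. Fry's either-direction call of the HuR ligands was also lost without the lower 50% (adjusted p = 0.054) and that of the histone and chromatin list with the replicate block (adjusted p = 0.0719). Over the alternatives these adjusted p ranged from 0.00248 to 0.523 and from 0.00248 to 0.379.

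Of named genes and list means that never passed in the main analysis, some changed sign. Leaving out arrays gave ranges of -0.06 to 0.03 for Khsrp, -0.115 to 0.005 for Plin2 and -0.005 to 0.095 for Pnpla2. For list means it gave -0.004 to 0.012 (HuR ligands), -0.011 to 0.051 (cytosolic ribosomal), -0.01 to 0.012 (G2/M), -0.012 to 0.014 (proteasome), -0.048 to 0.017 (glycolysis), -0.004 to 0.035 (heat shock), -0.007 to 0.028 (endoplasmic reticulum stress), -0.019 to 0.077 (cholesterol) and -0.019 to 0.014 (adipocyte). Without the lowest 25% by mean level the mRNA decay list was at 0.003, G2/M at -0.007 and immediate early genes at -0.011. Without the lower 50% mRNA decay was at 0.012, G2/M at -0.005 and glycolysis at 0.015. The mean of all clones gave -0.018 for Col5a1, 0.01 for Hmgb1 and -0.017 for the extracellular matrix list. Removing grid medians gave 0.025 for Khsrp, 0.032 for Psmc5 and 0.031 for adipocyte markers. Removing plate medians gave -0.008 for translation factors, -0.003 for G2/M and -0.01 for the proteasome, and leaving out spots at the most frequent value gave -0.012 for G2/M. The cause was not tested. The deposited scores carry no background. In the second section the spots described as empty had a median z-score of -1, with 10.6% of clone spots below it, but 19 of them had signal, and the first section has no such spots.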

Other observations

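The tests chosen or reworded only after the result was seen were all 3 of the source plate pattern, the grid test and the count of genes with more than 1 clone for Npm1, the random lists, the plate shifts, the count of lists called per split and the test without the strongest member for the HuR ligands, and the counts of the split by replicate number under other settings. Apart from Npm1, Ctsl, the lysosomal protease cathepsin L, was the other of 2 genes among 1916 with more than 1 clone whose clones all parted the arrays by siRNA by at least 0.205 z units. Ctsl was singled out after its values were seen. In the other 2 splits of the 4 arrays, no gene did so. These counts are not matched on plate. Both Npm1 clones came from the same source plate, while the clones of Ost4, for example, came from different sections. At any size, all clones of a gene parted the arrays one way for 78 genes (4.07%) by siRNA, 96 (5.01%) by replicate number and 44 (2.3%) in the crossed split. Across the 1916 genes, the siRNA differences of the 2 brightest clones correlated at a Spearman rho of 0.094 (Pearson's r 0.026), against a rho of 0.546 for their mean levels. In the 655 genes with both clones bright, the rho of the differences was 0.175 (r 0.168). Genes are not independent replicates. Where the arrays were split by replicate number or crossed, the rho was 0.008 and 0.047 across the 1916 genes, and 0.005 and 0.051 in the 655. Clones of the mitochondrial genome (160 spots) had a median difference of -0.007 and clones of 45S ribosomal RNA (24 spots) 0.008.

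When the 4 arrays were split by replicate number instead of siRNA, 1565 features had an unadjusted p under 0.05 and 2 passed the adjusted threshold, against 528 and 0 for the siRNA. The crossed split gave 306 and 0. The ratio of the first count to the second was 2.96. It was 1.71 after removal of grid medians, 2.9 without spots at the most frequent value, 1.85 in the first section and 6.07 in the second. The count points to a structure of the arrays other than the siRNA, given here as values with no explanation.

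The first pattern is that 5 of the 9 named lower genes came from source plate 57. This plate held 26 of the 329 features lower at an unadjusted p under 0.05 where 2 are expected. The excess was not confined to it: plates 70, 53 and 73, also of the first section, held 13, 12 and 12. Removing plate medians tests only an even shift of the whole plate. The differences of the 5 genes, -0.415 to -0.295 before, were then -0.332 to -0.212. All 5 of the 5 kept an unadjusted limma p under 0.05 (highest 0.023). Because these genes were picked for the smallest p, this excludes little, and a plate effect that varies by spot stays open. The 54 neighbouring clones had a median of -0.09 (95% bootstrap interval -0.16 to -0.035), lower than 0 but short of the -0.35 of the 5 genes, so an effect local to some wells may contribute and stays open. A change of the genes' mRNA with the siRNA stays open for single genes, but nothing here shows why such genes would share a plate. Of 14 genes with a symbol lower on this plate (median -0.305), 5 had clones from other plates, 7 clones with a median of 0.01 (interval -0.04 to 0.03), but these genes were picked for a low value and the differences of 2 clones of a gene correlate at a rho of 0.094, or 0.175 where both are bright, so this decides nothing.

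The second pattern is Npm1, higher on both clones, which came from the same source plate, 136. These clones lay in grids 302 and 304, within the grids where 19 of 28 spots described as empty had z-scores above 0. Whether this affects the Npm1 values was not tested. An even shift of the 2 grids is argued against by their 41 other spots, with a median of 0.035, although 3 of them reached 0.205 and the highest was 1.175. An effect shared by neighbouring wells is argued against by 17 clones with a median of 0.03 (interval 0 to 0.045), 0 of which reached 0.205. A local effect that varies from spot to spot stays open, since a median cannot show it. Chance stays open, since 2 genes in the siRNA split and 0 in the other splits are too few to decide, and at any size the split by replicate number gave more genes. That the mRNA differs with the siRNA is a hypothesis that may be followed up, with the limit that Elavl1 itself did not differ detectably.

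The third pattern is the change of HuR ligand mRNAs in either direction, a hypothesis that the siRNA may shift them both ways. The list's mean squared t lay at the 98.1th percentile of 10000 random lists matched on mean level, but adjusted over the 26 lists that gives 0.172, and the histone and chromatin list (99.4) and oxidative phosphorylation (98) lay as high or nearly so. Without Jun the percentile was 89.9 and fry's adjusted p 0.219, and without Hmgn2 the histone and chromatin list was at 36.8. Leaving out the strongest member lowers the value of any list, so these falls alone decide little. The histone and chromatin list rested mostly on Hmgn2 (84.3% of the summed squared t) and the HuR ligands less on Jun (30.7%). Of the 35 ligands, 4 had an unadjusted limma p under 0.05, against 3.75% of all features. In the other splits the list's smallest adjusted p was 0.604, but the split by replicate number called 4 lists where the siRNA split called 2, so a structure of the arrays unrelated to the siRNA stays open and that test excludes nothing. Shifts of source plates stay open: with plate medians removed the adjusted p was 0.122 and the percentile 93.2.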
